A study of Mus musculus with 20 samples.

How the data were processed

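RNA was measured by poly(A) sequencing in the livers of mice with diet-induced obesity. Per the labels, the mice received vehicle, rosuvastatin, geranylgeraniol (GGOH) or both compounds, and 5 mice of each of the 4 groups gave 20 libraries. The labels give no dose, time of sampling, sex or batch. Per the labels' protocols, total RNA was purified on RNeasy columns, libraries were made with the TruSeq mRNA chemistry, and paired reads were generated on a NovaSeq instrument. Per the submitters' processing notes, bcl2fastq 2.19, kallisto 0.44.0 and DESeq2 were used with the mouse build GRCm38; no version or role is given for DESeq2.

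The authors deposited a table of kallisto estimated counts per gene and a table of TPM values per gene, the latter scaled by the authors for transcript length and depth. Both hold 34934 entries, of which 1 has no gene name and took between 0.00801 and 0.0157% of a library's counts. That entry was left out of library sizes and tests. The deposited estimated counts were rounded to whole numbers before testing. Total estimated counts ran from 8548120 to 18373913 per library (median 15697884). kallisto divides reads among near-identical transcripts by estimation, so values of close paralogs (Cyp2b9, Cyp2b10 and Cyp2b13; Saa1 and Saa2; Cyp2a4; Gsta1) are uncertain as to which copy the reads came from. Gene positions were taken from GENCODE M21 on GRCm38.

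Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM normalisation, the default low-count filter by group (12789 genes kept) and 1 group-means model over all 20 libraries. P-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold. The contrasts were rosuvastatin against vehicle, GGOH against vehicle, the combination against rosuvastatin, against vehicle and against GGOH, and the interaction of the compounds. Reported log2 fold changes are the fitted ones, and the value after ± is their SE, derived from the F statistic. The common biological coefficient of variation was 0.300. Counts were also simulated for the same genes, with 200 genes changed and the cholesterol synthesis list raised 2-fold. In the 5 pairwise contrasts the test recovered between 43 and 58% of 2-fold changes and between 85 and 96% of 4-fold changes. It made 5 to 13 false calls. Each gene was drawn independently and without structure between libraries, so these rates may not hold for the real libraries.

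Before the data were examined, 20 gene lists and 14 cell type marker lists were fixed, and each was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of its kind. No pancreatic acinar marker passed the low-count filter, so 13 marker lists were tested. Camera was repeated with the correlation estimated from the data. The p-values of a list's members were also adjusted over that list alone, including lists that camera did not call. This was done for each list and comparison separately, with no correction across them, so a gene can pass there and fail over all genes. The mean log2 CPM of a list per mouse was compared by exact permutation of the 252 assignments of 10 mice to groups of 5, two-sided, whose smallest p is 0.00794. For the interaction, 100000 permutations were drawn.

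Genes named in the text follow a rule fixed in advance: a set of focal sterol, isoprenoid and glucose genes, genes past the threshold with an average log2 CPM of at least 1, the 5 smallest p-values where no gene passed, and up to 4 members of a called list. Gene models without an assigned name were counted but not named by this rule. Cyp2b9, Gm10171, Gm10233, Ccl2, Irs2 and Cyp2a4, and Saa1, Saa2 and Cyp2b10 where the rule does not name them, were chosen after their values were seen. The alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no low-count filter, a stricter filter (CPM of at least 1 in 5 libraries), only the groups compared, replicate number as a block, transcript length offsets, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), sample quality weights, fry, and leaving out each library. After the data were seen, 3 more were added: offsets for GC content and length, surrogate variables from sva 3.50.0, and a fit without 3 doubted libraries. The effect of each compound averaged over the other, the score per mouse and the count over the cholesterol list alone under each setting were also added then.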

Results

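Liver transcriptomes were compared between obese mice given vehicle, the statin rosuvastatin, the isoprenoid alcohol GGOH, or both, with 5 mice per group. The total estimated count per library was 14060978 ± 1552486 (SD, n = 5) with vehicle, 15410437 ± 915295 with rosuvastatin, 16198483 ± 2834636 with GGOH and 15453338 ± 3932208 with the combination. Mitochondrial transcripts took 27.9% and 29.2% of the counts in combination mice 2 and 3, against at most 17.1% in the other 18 libraries. The first principal component held 36.1% of the variance, and 20.5% of it lay between groups (permutation p = 0.286). All 10 libraries with rosuvastatin had a positive correlation across genes between expression deviation and GC content, as had 3 of the 10 without it. The difference in that correlation between libraries with and without rosuvastatin, averaged over GGOH, was 0.318 (exact permutation p = 0.00479). This test was chosen after the data were seen, and its p does not allow for that choice. Genes are not independent replicates, and the test permuted mice.

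**Figure D1:**
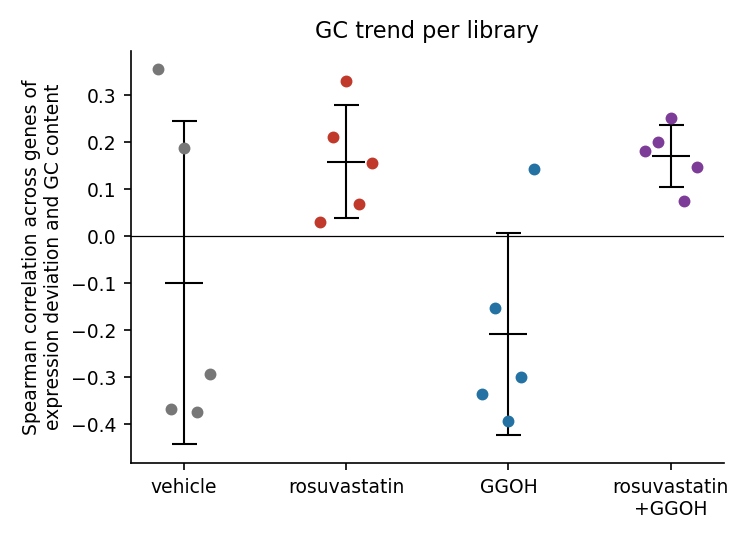
Each point is 1 library, and the y axis is the Spearman correlation across genes between a library's deviation from the mean log2 CPM and gene GC content. Bars show the mean and SD of 5 mice per group, and all 10 libraries with rosuvastatin lie above 0.

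Rosuvastatin was compared with vehicle to ask how the statin changes the liver of obese mice. Genes of cholesterol synthesis were higher with the statin: 19 of 20 had a positive change, with a median log2 fold change of 1.11, and 17 passed when adjusted over the list alone. Fdps, which makes farnesyl diphosphate and lies on chromosome 3 from 89093588 to 89101959, stood at 123 ± 85.2 CPM (SD, n = 5) against 39.2 ± 27.1 with vehicle. The log2 fold change was 1.64 ± 0.51 (SE) for Fdps, 1.64 ± 0.55 for Mvd and 1.38 ± 0.62 for Sqle. The camera adjusted p of the list was 3.87e-23, and adjusted p = 0.226 with an estimated correlation.

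The fatty acid and triglyceride synthesis list also rose by camera (median 0.29, adjusted p = 3.97e-06), as did sterol-regulated uptake and control (0.40, adjusted p = 0.000809) and NRF2 targets (0.22, adjusted p = 0.00841). Each had adjusted p = 0.486 with an estimated correlation, and 0 of their members passed when adjusted over the list alone. The sterol uptake call ended without rosuvastatin mouse 4 (adjusted p = 0.0510). The NRF2 call ended without vehicle mouse 3 or rosuvastatin mouse 5 (highest adjusted p = 0.206), and without vehicle mouse 1 and combination mice 2 and 3 together (0.0518), a set chosen after seeing the data. The log2 fold change was 0.95 ± 0.40 for Fasn, the fatty acid synthase. In the isoprenoid branch, Ggps1, which makes geranylgeranyl diphosphate, was at -0.39 ± 0.20.

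By edgeR, 0 of 12789 genes passed over all genes (smallest adjusted p = 0.973), with 472 at an unadjusted p under 0.05 against 639 expected by chance. DESeq2 called 2 genes, Nfe2 (log2 fold change 3.02) and Prg4 (-1.60), both at adjusted p = 0.0439, and each other tool called 0. Among genes with an assigned name, the smallest edgeR p-values after those of Prg4 and Nfe2 belonged to Zfp268 (1.83 ± 0.45), Cib3 (2.32 ± 0.58) and Olfr624 (-0.91 ± 0.25). The score per mouse of the cholesterol list differed by 1.01 (exact permutation p = 0.0794). The count of 17 became 0 without vehicle mouse 3, vehicle mouse 5 or rosuvastatin mouse 3, and 7 with sample quality weights.

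**Figure D2:**
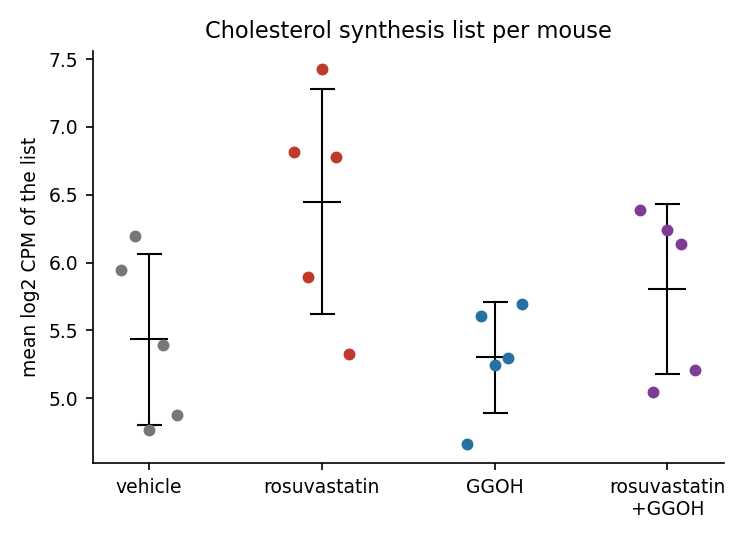
Each point is 1 mouse, and the y axis is the mean log2 CPM of the 20 cholesterol synthesis genes. Bars show the mean and SD of 5 mice per group; vehicle averaged 5.43 and rosuvastatin 6.45.

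GGOH alone was compared with vehicle to measure the effect of the isoprenoid without the statin. Fatty acid oxidation and PPAR-alpha targets rose by camera (median 0.17, adjusted p = 6.19e-05), with 18 of 24 members higher, and adjusted p = 0.468 with an estimated correlation. Fgf21, a hepatic fasting hormone in that list, was at 1.18 ± 0.42 and Ehhadh at 0.55 ± 0.23. Interferon response (0.30, adjusted p = 0.00347), cell cycle (0.27, 0.00484), NRF2 targets (0.23, 0.00509), respiratory chain (0.09, 0.0180) and fatty acid synthesis (0.14, 0.0197) rose by camera as well. Sterol-regulated uptake and control (-0.38, adjusted p = 0.00627) and the circadian clock (-0.30, adjusted p = 0.0164) fell, and all 7 had adjusted p = 0.468 with an estimated correlation.

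Over all genes, 0 passed in this comparison. When adjusted over each list alone, with no correction across lists, 7 genes passed. They were Elovl6 (1.18 ± 0.35) and Me1 (0.67 ± 0.20) of fatty acid synthesis, the clock gene Per1 (-2.02 ± 0.57) and Cyp2b10 (1.76 ± 0.51) of xenobiotic metabolism. The others belong to the inflammation list, where the chemokine Ccl2 was higher (1.31 ± 0.44) and the acute phase genes Saa1 (-3.61 ± 0.99) and Saa2 (-4.13 ± 1.06) were lower. Without vehicle mouse 2, which had 9216 CPM of Saa1, they were at -1.91 and -2.19 (edgeR unadjusted p = 0.0258 and 0.0150). Their adjusted p over all genes was then 0.825, which cannot be set against the list-alone result above. The adjustment over the list alone was not repeated without that mouse. Cholesterol synthesis had a median of -0.26 (camera adjusted p = 0.124). Markers of neutrophils, lipid-associated macrophages and Kupffer cells were higher (medians 0.61, 0.31 and 0.30) and those of sinusoidal endothelium lower (-0.18), at camera adjusted p between 0.0479 and 0.0490. The neutrophil list held only 5 tested markers. With an estimated correlation the adjusted p was 0.724 to 0.749, and each of these marker calls ended without any 1 of 11 to 14 of the 20 libraries (highest adjusted p = 0.958, Kupffer cells without GGOH mouse 2, where the list turned lower). By edgeR, 0 genes passed (smallest adjusted p = 1.00), with 366 at an unadjusted p under 0.05, and DESeq2 and limma called 0. The smallest p-values belonged to Ahr (-0.58 ± 0.15), the sensor of aryl hydrocarbons, Prg4 (-1.37 ± 0.35), Bbx (-0.89 ± 0.23), Saa2 and Art2b (2.01 ± 0.53). Of the 8 list calls, that of the oxidation list was the only 1 kept without each of the 20 libraries. The others ended without 1 or more of the vehicle or GGOH mice, with the highest adjusted p, 0.683, for the respiratory chain without vehicle mouse 1, and 0.617 for interferon without GGOH mouse 2. With GC content and length offset, a setting chosen after seeing the data, the respiratory chain (adjusted p = 0.196) and the 4 marker calls (0.0621 to 0.277) ended too. Without vehicle mouse 1 and combination mice 2 and 3, left out together after seeing the data, the calls of sterol uptake (0.194), clock (0.172), respiratory chain (0.585), Kupffer cells (0.0973) and neutrophils (0.239) ended.

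The combination was compared with rosuvastatin alone to ask what adding GGOH changes under the statin. All 20 cholesterol synthesis genes were lower, with a median of -0.82 and camera adjusted p = 5.81e-18. The list had adjusted p = 0.221 with an estimated correlation, and 0 members passed when adjusted over the list alone. Its score per mouse differed by -0.64 (exact permutation p = 0.190). The rosuvastatin mice are those of the first comparison, so the rise there and the fall here are not independent. High values by chance in that group would give both. Fdps stood at 63.3 ± 32.2 CPM (SD, n = 5) with the combination. The log2 fold change was -1.20 ± 0.61 for Sqle.

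The xenobiotic metabolism list rose by camera (median 0.10, 13 of 18 members higher, adjusted p = 1.59e-05, and adjusted p = 0.213 with an estimated correlation), and Cyp2b10 and Cyp2c29 passed when adjusted over the list alone. Cyp2b10, a cytochrome P450 induced through the receptor CAR, on chromosome 7 from 25897620 to 25926624, stood at 6.04 ± 2.36 CPM (SD, n = 5) against 0.752 ± 0.569. Its log2 fold change was 2.98 ± 0.50 with edgeR adjusted p = 0.0714, and DESeq2 gave adjusted p = 7.99e-06. Cyp2c29 stood at 647 ± 122 against 353 ± 77.0 CPM. Cyp2b9, a near-identical neighbour, stood at 127 ± 65.8 against 87.9 ± 65.0 CPM.

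Handling and immediate early genes rose by camera (median 0.54, adjusted p = 0.000303, and adjusted p = 0.503 with an estimated correlation), a call that ended without combination mouse 5 (adjusted p = 0.155). Sterol-regulated uptake and control (-0.31, adjusted p = 0.00472), fibrosis and matrix (-0.23, 0.00619) and inflammation and acute phase (-0.10, 0.0124) fell, each with adjusted p = 0.739 with an estimated correlation. Each call ended without rosuvastatin mouse 3, and others ended them too: rosuvastatin mouse 4 and combination mouse 5 for sterol uptake, rosuvastatin mouse 5 and combination mouse 1 for fibrosis (highest adjusted p = 0.961), and rosuvastatin mouse 1 and combination mice 1 and 2 for inflammation (0.592). The inflammation call also ended once GC content and length were offset (adjusted p = 0.130) and without vehicle mouse 1 and combination mice 2 and 3 (0.678), settings chosen after seeing the data. Both settings ended the 2 marker calls below as well, and the second ended the fibrosis call (0.139). Markers of lipid-associated macrophages (-0.21, adjusted p = 0.0263) and cholangiocytes (-0.58, 0.0394) were lower, with adjusted p = 0.406 with an estimated correlation. Their calls ended without any 1 of 7 and 12 libraries (highest adjusted p = 0.430, cholangiocytes without rosuvastatin mouse 3). The cholangiocyte list held only 4 tested markers at a low level, with mean scores of 0.21 log2 CPM with rosuvastatin and -0.35 with the combination. Spp1, which is also a member of the fibrosis and matrix list, passed when adjusted over the macrophage list alone (-1.29 ± 0.39). It therefore does not single out macrophages. By edgeR, 0 genes passed and 216 were at an unadjusted p under 0.05. DESeq2 and limma on log2(TPM + 1) each called 1 gene, Cyp2b10, and edgeR did so without vehicle mouse 4 (adjusted p = 0.0301) or rosuvastatin mouse 5 (0.0140). Among genes with an assigned name, after Cyp2b10 and Cyp2c29 the smallest p-values belonged to Ptk7 (-1.86 ± 0.54), Ahr (-0.48 ± 0.15) and Spp1.

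The combination was compared with vehicle for its net effect. Cyp2b10 stood at 6.04 CPM against 0.713 ± 0.443 (SD, n = 5), a log2 fold change of 3.03 ± 0.51 with edgeR adjusted p = 0.0783, and 9.29e-06 by DESeq2. The acute phase genes Saa1 (-4.37 ± 1.02) and Saa2 (-4.53 ± 1.08) passed when adjusted over the inflammation list alone, as did Cyp2b10, Cyp2c29 (0.73 ± 0.22) and Cyp2a4 (2.30 ± 0.73) over the xenobiotic list alone. Saa1 averaged 2443 ± 3820 CPM (SD, n = 5) with vehicle, of which vehicle mouse 2 had 9216. Without that mouse the log2 fold change was -2.64 for Saa1 and -2.56 for Saa2, and the adjustment over the list alone was not repeated. Fatty acid synthesis rose by camera (median 0.42, adjusted p = 1.45e-05), as did NRF2 targets (0.32, 0.0172), cholesterol synthesis (0.32, 0.0211) and handling genes (0.45, 0.0389). Inflammation and acute phase fell (-0.11, adjusted p = 0.0240), and all 5 had adjusted p = 0.880 with an estimated correlation. With GC offsets the adjusted p was 0.298 for inflammation and 0.114 for handling genes, and without the 3 libraries named above it was 0.142 for inflammation. The fatty acid call was the only 1 of the 5 kept without each of the 20 libraries, and the others reached an adjusted p of up to 0.573 (handling genes without combination mouse 5) and 0.472 (cholesterol without vehicle mouse 3). By edgeR, 0 genes passed and 704 were at an unadjusted p under 0.05. DESeq2 called 5 (Cyp2b10, Saa1, Saa2, Gm10171 and Gm10233), and both limma fits on TPM called 1, Cyp2b10. edgeR called it without rosuvastatin mouse 3 (adjusted p = 0.0437) or 5 (0.0227). Gm10171 and Gm10233 have the same count as each other in every library. Gem (-0.84 ± 0.20) and Csad (0.95 ± 0.23) completed the 5 smallest edgeR p-values of genes with an assigned name.

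**Figure D3:**
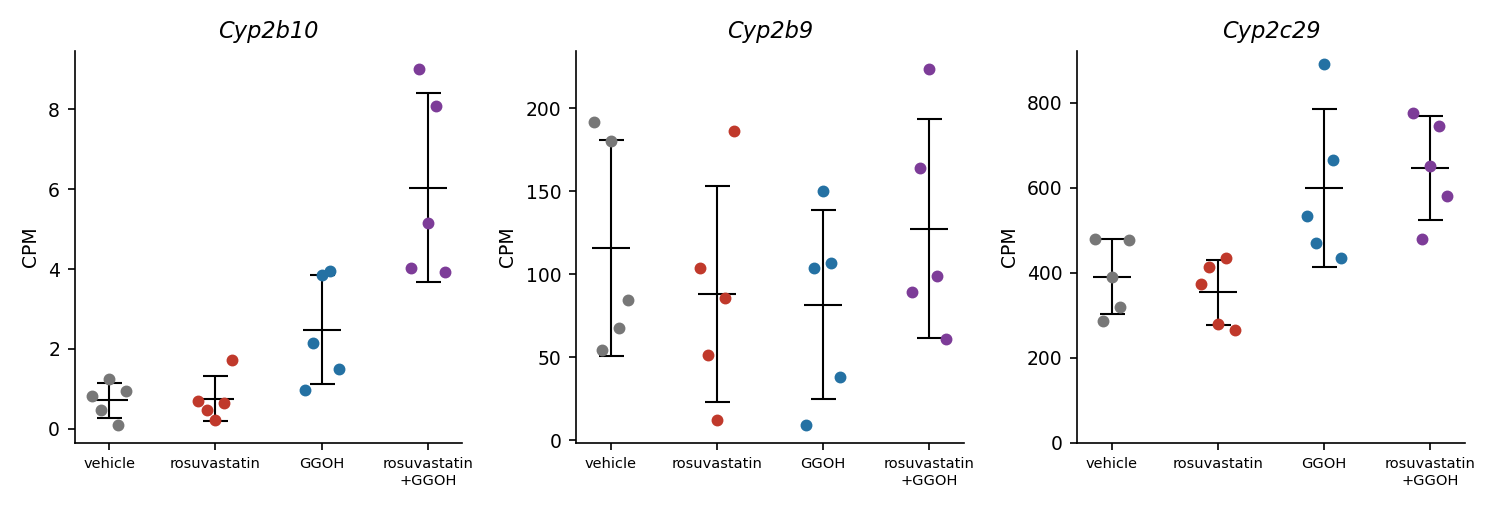
Each point is 1 mouse, with CPM on the y axis, for Cyp2b10, Cyp2b9 and Cyp2c29. Bars show the mean and SD of 5 mice per group; Cyp2b10 averaged 0.713 CPM with vehicle and 6.04 with the combination.

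The combination was compared with GGOH to measure the statin in its presence, in mice that the first comparison did not use. Cholesterol synthesis rose by camera (median 0.58, 19 of 20 members higher, adjusted p = 0.00945), as did sterol-regulated uptake and control (0.51, 0.0160) and LXR targets (0.25, 0.0325). The respiratory chain (-0.19, adjusted p = 0.0160), inflammation (-0.39, 0.0308) and fatty acid oxidation (-0.21, 0.0325) fell, and all 6 had adjusted p = 0.786 with an estimated correlation. Without GGOH mouse 1, 0 of the 6 passed. With GC offsets 5 of these 6 calls ended: sterol uptake (adjusted p = 0.0882), LXR targets, fatty acid oxidation and the respiratory chain (0.173 each) and inflammation (0.405). Without vehicle mouse 1 and combination mice 2 and 3 the adjusted p was 0.662 for the respiratory chain and 0.231 for inflammation. The mean share of mitochondrial transcripts was 19.4% with the combination and 12.9% with GGOH, and the first was carried by combination mice 2 and 3, as the others had 17.1, 13.4 and 9.12%. The log2 fold change was 1.13 ± 0.45 for Lss, and Irs2, an adaptor of the insulin receptor (1.01 ± 0.30), passed when adjusted over the gluconeogenesis and insulin list alone. By edgeR, 0 genes passed (smallest adjusted p = 0.348), with 1788 at an unadjusted p under 0.05, and DESeq2 and limma called 0. Among genes with an assigned name, the smallest p-values belonged to Gmeb1 (0.88 ± 0.20), Shroom1 (0.91 ± 0.21), Top3b (0.75 ± 0.17), H2-K2 (1.22 ± 0.29) and Ushbp1 (1.02 ± 0.25). Across genes the statin's fold changes with and without GGOH had a Pearson r of 0.251 (jackknife SE 0.354), and those of GGOH with and without the statin -0.129 (SE 0.260). The Spearman correlations were 0.386 and -0.236, and 66.0% and 41.4% of genes had the same sign. The mean GC correlation was 0.159 with rosuvastatin against -0.0988 with vehicle, and 0.170 with the combination against -0.208 with GGOH. This shift, shared by both statin contrasts, could by itself raise their r.

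The interaction tested whether the statin effect differed with GGOH. Cholesterol synthesis was lower (median -0.52, 18 of 20 members, camera adjusted p = 0.000517), as were the interferon (-0.30) and cell cycle (-0.50) lists, both at 0.00513. Each had adjusted p = 0.536 with an estimated correlation. Markers of lipid-associated macrophages (-0.58, adjusted p = 0.00201) and Kupffer cells (-0.50, 0.0241) were lower too, with adjusted p = 0.747 with an estimated correlation. The cholesterol call ended without rosuvastatin mouse 3 (adjusted p = 0.125), interferon without vehicle mouse 5, GGOH mouse 2 (0.294) or combination mouse 1, and cell cycle without vehicle mouse 5, rosuvastatin mouse 5 (0.0933) or combination mouse 1. The Kupffer call ended without any 1 of 8 libraries (highest adjusted p = 0.659), with GC offsets (0.0683) and without vehicle mouse 1 and combination mice 2 and 3 (0.152). By edgeR, 0 genes passed and 369 were at an unadjusted p under 0.05, and DESeq2 and limma called 0. Among genes with an assigned name, the smallest p-values belonged to Tlr5 (4.58 ± 1.13), Setbp1 (2.58 ± 0.73), Snx20 (-1.50 ± 0.42), Prg4 (1.70 ± 0.49) and Zfp268 (-2.07 ± 0.61).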

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

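The tests in this part were chosen after the result was seen, except the splits of the mice that counted genes in the 6 comparisons and the splits of the averaged effects, whose contrasts were themselves added after seeing the data. A count of splits for the p of Cyp2b10 alone was set aside as void, because the gene had been picked for that p, and splits with quality weights were limited to 60 for computing time. In 188 groups of 5 values, 9 had a mouse far from the others, against 9.4 by chance, and these come first. Combination mouse 3 had a total of 8548120 counts, an isoprenoid list score of 3.38 and an adipocyte list score of 2.48. Rosuvastatin mouse 3 had an ER stress score of 5.27 and a respiratory chain score of 7.06. Rosuvastatin mouse 5 had an NRF2 score of 5.68 and an adipocyte score of 2.88. Vehicle mouse 1 had 16776626 counts and GGOH mouse 1 had 11350411. By camera, the statin effect differed with and without GGOH for cholesterol synthesis (adjusted p = 0.000517), interferon response and cell cycle (0.00513 each). The same held for lipid-associated macrophages (0.00201) and Kupffer cells (0.0241). With an estimated correlation the camera adjusted p was 0.536 for the gene lists and 0.747 for the marker lists. By score per mouse the permutation p of the interaction was 0.351, 0.298, 0.154, 0.144 and 0.579, in the order of the lists above.

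Cholesterol synthesis genes were higher with rosuvastatin than with vehicle. Once a trend on GC content and transcript length was removed from each library, the list median was 1.07 against 1.11, and 17 members still passed over the list alone. These values argue against the trend as the whole cause. Without the 3 doubted libraries (vehicle mouse 1 and combination mice 2 and 3) the median was 1.16, with 18 members. That fit cannot decide whether those libraries were the cause, as only vehicle mouse 1 belongs to the compared groups. Its list score of 5.94 lay above the vehicle mean of 5.43, so leaving it out could only widen the difference in score. Chance could not be excluded, as 8 of 100 splits of the 10 mice, the real one included here and in all counts of splits below, gave a camera p as small as 1.94e-24 (smallest of the others 2.41e-78), and 17 of 100 for the averaged effect (7.70e-14, others down to 7.72e-93). A response to the statin may underlie the list and stays open as a hypothesis.

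Cyp2b10 was higher with GGOH averaged over rosuvastatin (log2 fold change 2.37 ± 0.35), and Cyp2b9, which would rise alike if a constant share of its reads were the cause, was at 0.0152 ± 0.43. A changed division of reads between the genes could not be decided, as Cyp2b10 rose by 3.53 CPM and the smallest SD of Cyp2b9 in a group was 56.8 CPM. After GC content and length were removed, Cyp2b10 stood at 2.33 ± 0.36 (adjusted p = 0.0212). However, its call ended without the 3 doubted libraries (adjusted p = 0.206, log2 fold change 2.31, fewer mice). It also ended with replicate number as a block and in 6 of 20 fits without 1 library. Chance could not be decided for the count of called genes: 2 of 100 splits gave 1 gene or more, with a real value of 1 and a highest other value of 1, but the contrast was added after this gene stood out. A broader response of xenobiotic genes may accompany it but could not be decided, as the other 17 members had a score difference of 0.17 (exact permutation p = 0.256).

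With sample quality weights, 1594 genes differed with rosuvastatin averaged over GGOH. With weights estimated in the same way before and after, 1527 genes were called before and 0 after the GC and length trend was removed, and 4236 and 2009 were at an unadjusted p under 0.05, against 639 expected by chance. The SD of the log2 fold change over genes went from 0.37 to 0.28, its median SE from 0.15 to 0.14, its rank correlation with GC content across genes from 0.487 to 0.0391 and the cholesterol list median from 0.69 to 0.79, so the trend may underlie part of the calls. Chance could not be decided: 2 of 60 splits gave as many genes, the real one and 1 with 2300, which points to a structure of the samples, but the setting and contrast were picked after the count was seen. No label gives an order of preparation, so whether the trend came with the drug or with handling was not tested.

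Chance could not be decided for any count of genes in the 6 comparisons, where the real count was 0 and 100 of 100 splits gave as many, as any split must. The highest other counts were 3026 for rosuvastatin against vehicle, 3275 for GGOH against vehicle, 444 for the combination against rosuvastatin, 4415 against vehicle, 4 against GGOH and 5152 for the interaction, and counts over 100 point to a structure of the samples. For rosuvastatin averaged over GGOH the real count was 0 and the highest other 9. At an unadjusted p under 0.05, 2 of 100 splits, the real one included, gave as many as the 1841 genes of that contrast (highest other 2780), and 9 as many as the 1788 of the combination against GGOH (3176), values looked at after the data. Chance could not be excluded for the counts of lists either: 83 of 100 splits gave at least the 4 lists of rosuvastatin against vehicle (highest other 13), 19 the 8 of GGOH against vehicle (11), 51 the 6 of the combination against rosuvastatin (13), 45 the 5 against vehicle (10), 51 the 6 against GGOH (13) and 88 the 3 of the interaction (11). It was 42 for the 7 lists of GGOH averaged (14) and 73 for the 5 of rosuvastatin averaged (14).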

How the results depend on the processing

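Results on averaged effects and on the cholesterol list alone, and the GC offsets, surrogate variables, doubted libraries and scores per mouse, were chosen after seeing the data. The counts of 0 genes held under the other settings except these. DESeq2 gave 2 genes for rosuvastatin against vehicle, and 1, 5, 4 and 13 for the combination against rosuvastatin, the combination against vehicle, GGOH averaged and rosuvastatin averaged. No low-count filter, transcript length offsets and log2(TPM + 1) each gave 1 gene for the combination against rosuvastatin and 1 against vehicle, and log2(TPM + 0.1) gave 1 against vehicle. Surrogate variables gave 1, 1, 4 and 2 genes for the combination against rosuvastatin, against vehicle (Per1 rather than Cyp2b10), GGOH averaged and rosuvastatin averaged. Quality weights gave 3 and 1594 for the averaged effects, and GC offsets 2 for GGOH averaged. For GGOH averaged, the replicate block gave 0 (Cyp2b10 2.33, adjusted p = 0.196) and the fit without the doubted libraries 0. Leaving out 1 library gave 0 to 1 gene for the combination against rosuvastatin and against vehicle, and 0 (without vehicle mouse 2, for example) to 2 for GGOH averaged, where Cyp2b10 ranged in adjusted p from 0.00236 to 0.0594.

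The lists called numbered 0 in all 8 contrasts with an estimated correlation, by fry and by score per mouse. GC offsets gave 1 list for the combination against GGOH, 7 for the interaction and 3 for rosuvastatin averaged, and the fit without the doubted libraries gave 8 for the interaction. Leaving out 1 library gave 3 to 7 lists for rosuvastatin against vehicle (without vehicle mice 3 and 2), 6 to 12 for GGOH against vehicle, 3 to 9 for the combination against rosuvastatin, 2 to 7 against vehicle, 0 to 9 against GGOH, 1 to 12 for the interaction, 6 to 11 for GGOH averaged and 3 to 8 for rosuvastatin averaged. The cholesterol count over the list alone was 7 with quality weights and 0 to 18 over left-out libraries, and the averaged one was 4 with the replicate block. The correlation of GGOH fold changes reversed to 0.131 with quality weights, 0.0875 with surrogate variables, 0.0150 without the doubted libraries and 0.0161 without vehicle mouse 1 (lowest -0.213), and that of the statin ranged from 0.0632 to 0.427 over left-out libraries. The Kupffer cells and macrophages list, GGOH against vehicle, reversed without GGOH mouse 2 (adjusted p = 0.958, and 5.06e-05 at the lowest, without GGOH mouse 5). The cause was not tested for these changes, except that fewer libraries enter some fits. The replicate numbers were not taken as pairs, as not every same-numbered pair correlated: 13 of 30 had a correlation of deviations over 0.1 (median 0.0560, against 0.0222 for other pairs), and 5 of 20 libraries matched best with their own number. The block gave 0 genes in the 6 comparisons and moved no count of gene lists by over 1.5 times. It ended the calls of Kupffer cells (adjusted p = 0.0858), lipid-associated macrophages and sinusoidal endothelium (0.0593 each) and neutrophils (0.0610) for GGOH against vehicle, cholangiocytes for the combination against rosuvastatin (0.0504) and handling genes against vehicle (0.0892). Values on log2(TPM + 1) and log2(TPM + 0.1) shifted the median of all genes by 0.15 and 0.19 for rosuvastatin against vehicle and by -0.12 and -0.16 for the interaction, and with 0.1 added by 0.10 for GGOH against vehicle and 0.12 for the combination against vehicle. In counts simulated at this depth and spread, with genes drawn independently, a 2-fold change was found in 43 to 58% of genes. The simulation held no structure between libraries, so the rate in the real data may differ.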

Other observations

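The averaged effects below, and the tests on them, were chosen after the results of the 6 comparisons were seen. Averaged over rosuvastatin, GGOH raised 1 gene by edgeR: Cyp2b10, with a log2 fold change of 2.37 ± 0.35 (5.17-fold, adjusted p = 0.0155). For this gene, 8 of the 10 mice with GGOH lay above every mouse without it. The gene was picked for its p in these same mice, so that separation adds no support to the call. The call ended with replicate number as a block, without the 3 doubted libraries (adjusted p = 0.206) and in 6 of the 20 fits without 1 library. The next smallest p-values belonged to Ahr (-0.53) and Cyp2c29 (0.74), which did not pass. DESeq2 called 4 genes, adding Ahr, Cyp2c29 and Saa2. By camera 7 lists differed in this contrast. Cholesterol synthesis (median -0.54, adjusted p = 5.03e-14) and sterol-regulated uptake and control (-0.24, 3.87e-06) were lower, and fatty acid oxidation (0.10, 3.87e-06), xenobiotic metabolism (0.03, 4.33e-06) and handling genes (0.44, 6.67e-06) higher, each with adjusted p = 0.158 with an estimated correlation. NRF2 targets (0.16, adjusted p = 0.00749) and fatty acid synthesis (0.10, 0.0295) were higher too, with adjusted p = 0.341 and 0.665 with an estimated correlation. The 4 tested cholangiocyte markers were lower (-0.40, camera adjusted p = 0.0179, and 0.592 with an estimated correlation). Leaving out 1 library ended the call of NRF2 targets in 2 of 20 fits, of fatty acid synthesis in 10 and of cholangiocytes in 7. Without the 3 doubted libraries the adjusted p was 0.227 for fatty acid synthesis and 0.349 for cholangiocytes, whose call also ended with GC offsets (0.0724). A rise of the handling list, kept without each of the 20 libraries, leaves handling of the GGOH mice as a possible cause of differences in this contrast. The handling score per mouse had an exact permutation p = 0.108, or 0.594 after adjustment. The smallest p of a score was that of fatty acid oxidation, 0.0104, or 0.207 after adjustment. Those of the other called gene lists ran from 0.0803 (xenobiotic metabolism) to 0.441 (fatty acid synthesis). Averaged over GGOH, rosuvastatin changed 0 genes by edgeR, with 1841 at an unadjusted p under 0.05, and DESeq2 called 13. By camera 5 lists differed: cholesterol synthesis (median 0.82, adjusted p = 1.54e-12), sterol-regulated uptake and control (0.38, 0.000452), fatty acid synthesis (0.28, 0.000452) and LXR targets (0.18, 0.0450) were higher, each with adjusted p = 0.734 with an estimated correlation, and the respiratory chain lower (-0.16, 0.0207, and 0.777). The LXR call ended in 8 of 20 fits without 1 library and with GC offsets (0.264), and the respiratory chain call in 4 fits, with GC offsets (0.183) and without the doubted libraries (0.111). In this contrast, 18 of the 20 cholesterol synthesis genes passed when adjusted over the list alone, and 4 did with replicate number as a block. The score per mouse differed by 0.76 (exact permutation p = 0.0184, or 0.132 after adjustment).

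The lists below passed in no comparison. The smallest camera adjusted p over the 6 comparisons was 0.0718 for gluconeogenesis and insulin signalling, 0.110 for bile acid synthesis and transport, 0.168 for ER stress, 0.186 for YAP and TAZ targets and 0.337 for the isoprenoid branch and prenylation. For markers it was 0.0759 for T and NK cells and for pericentral hepatocytes, 0.118 for B cells and for muscle, 0.200 for stellate cells, 0.296 for periportal hepatocytes, 0.463 for adipocytes and 0.534 for erythroid cells. In 27 of 198 tests of a list the median, mean and test differed in sign, and this held for 0 of the 40 called lists.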
